A study of Danio rerio with 2 samples.

How the data were processed

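RNA was sequenced from Cldnk:GFP-positive cells that had been sorted by flow cytometry from 5-day-old zebrafish larvae, either wild type or mutant for rraga. Per the labels, the 1 record of each genotype merges 2 independent biological replicates. The processed data used here were 1 table of the authors' own comparison, titled as mutant against control, with 34326 genes. The direction of each fold rests on that title. The reads were placed on the build GRCz11, per the submitters' processing notes. The aligner, the counting tool, the gene annotation release, the normalization and the statistical test are not given in the sources used here.

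For each gene the authors' table holds, per the file headers, a name, an Ensembl identifier, a region, the maximum group mean, a log2 fold change, a signed linear fold change, a p-value, an FDR p-value and a Bonferroni p-value. The maximum group mean was deposited as a normalized expression signal whose unit is not named, and it is called the level here. It is the higher of the genotype means, so neither genotype's own mean is given. The authors gave no fold and no p to 8569 genes of level 0, which hold a spreadsheet error in the deposited log2 and p-value columns, and 25757 genes remained. The deposited signed fold equals 2 to the power of the absolute log2 fold with its sign. The authors' FDR p-value matched the Benjamini-Hochberg adjustment of their p-value over 34326 genes, with a missing p taken as 1. The largest difference was 1.28e-04 over all genes and 9.89e-17 over the genes with an FDR p-value under 0.05. The table gives no count or depth, so the depth per sample is unknown and no counting interval was made. A count model, a refit with another normalization, a paired fit and leaving out a replicate all need values per replicate, and none was run.

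A gene was called changed where the authors' FDR p-value was under 0.05, as planned for a table that holds only the authors' test. To express precision, a standard error was derived from each deposited log2 fold and p-value as the absolute fold divided by the normal deviate of the two-sided p. This assumes a normal test. Because the authors' test is not given, it is not known whether their p, and so this error, carries the spread between replicates. Its median was 0.56 on the log2 scale for the 944 genes of level 100 or more, which is a 95% half-width of 1.11, or 2.15-fold, and a gene of such precision needed a 4.68-fold difference to pass the threshold. The median was 0.70 at levels of 10 to 30, 1.04 at 3 to 10 and 2.02 under 1, and no gene under level 3 passed. The median log2 fold of all genes was 0.02, that of the 5792 genes of level 10 or more was 0.15 and that of genes of level 100 or more was 0.11. Random lists matched on level carry the same shift as the gene lists they are compared with.

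Gene lists were fixed before the data were examined, with 14 for pathways, 11 for cell types and 1 for dissociation and stress. The pathway lists were lysosomal hydrolases and membrane proteins, v-ATPase subunits, autophagy and MiT-TFE factors, the Rag-Ragulator, FLCN and mTORC1 pathway, myelin and mature oligodendrocyte genes, oligodendrocyte lineage and precursor genes, cholesterol and fatty acid synthesis, ATF4 and amino acid response, endoplasmic reticulum chaperones, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, and DNA replication and mitosis. The cell type lists were macrophages, neurons, radial glia, Schwann cells and neural crest, pigment cells, epidermis, skeletal muscle, erythrocytes, endothelium, photoreceptors and lens, and exocrine pancreas, liver and gut. Of 1039 listed members, 991 were found (790 by name, 176 by a name pattern, 20 by Ensembl identifier and 5 by name in another case), 48 were not, and 984 had a p. For each list the median log2 fold was placed among the medians of 10000 random lists of the same size, drawn from 20 classes of level, and the authors' p-value was adjusted over the list alone by the Benjamini-Hochberg method. In 50 simulated lists of 30 genes of level 10 or more, a shift of 1 on the log2 scale was placed above the central 95% in 100% of lists, a shift of 0.5 in 92%, and with no shift 2% lay above and 4% below. The simulated lists held random genes with independent noise for each gene. Genes of a real list vary together, so these shares do not calibrate the percentiles of the real lists. Another 6 lists were added after the data had been seen and are used only for the closing observations.

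The genes named in the text were chosen by a rule fixed before the data were examined. They are rraga, the 10 largest rises and 10 largest falls among changed genes with a level at or above the median (1.75) and a symbol that is not a clone identifier, and for each list up to 4 changed members with the smallest adjusted p or, where none changed, the 2 of highest level. Other genes are said to be chosen after their values were seen, or are the members that passed the adjustment over a list alone. The alternatives tried were an absolute log2 fold of at least 1, an FDR p under 0.01, adjustment over genes of level 1 or more and 10 or more, and random lists not matched on level. Adjustment over genes with a p only, the authors' Bonferroni p and list members of level 10 or more were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.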

Results

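Oligodendrocytes, the myelin-forming glia of the central nervous system, were sorted from 5-day-old zebrafish larvae of the TL strain as cells carrying GFP under the Cldnk promoter, and their RNA was sequenced. The groups were wild type and rraga mutant, with 1 record per genotype, and each record merged 2 independent biological replicates per the labels. rraga encodes RagA, a small GTPase of the Rag-Ragulator complex on the lysosome surface, and the series title names the lysosomal transcription factor TFEB downstream of that complex. The comparison asked which transcripts differ in these cells when rraga is mutated. The values came as the authors' comparison of the genotypes, with a fold and a p per gene and no value per replicate, so no replicate spread is given and the sequencing depth is unknown. Expression is given as a level, the higher of the genotype means, in a normalized unit that the table does not name.

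In rraga mutant cells, all but 1 of the 25 measured subunits of the v-ATPase, the proton pump that acidifies lysosomes, had a higher value than in wild type, with a median log2 fold of 1.17 and 0 past the threshold. Of 79 lysosomal hydrolase and membrane protein genes, 63 were higher, with a median of 0.87 and 2 past the threshold. Erythrocyte genes had a median of 1.51, stress response genes 0.44, genes of the digestive organs -0.55 and macrophage markers 0.16. The autophagy receptor gene sqstm1 and flcn, which encodes folliculin, a regulator of the Rag GTPases, rose as well. The 38 myelin genes had a median of -0.23, and among them mpz fell and hapln2 rose.

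The mutated gene itself, rraga (ENSDARG00000104149, chromosome 14, 13738230 to 13788843, GRCz11), had a log2 fold of 0.44 at a level of 33.1 in the authors' deposited table, with p = 0.477 and an FDR adjusted p of 0.9999. The table does not say whether the mutant allele is still transcribed, so this value is no check of the genotype labels.

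Of 25757 genes with a p in the authors' deposited table, 57 had an FDR adjusted p under 0.05, of which 34 were higher and 23 lower in the mutant. The split ran the other way among the 2489 genes whose unadjusted p from the authors was under 0.05, with 1140 higher and 1349 lower. By chance alone 1288 genes were expected under that p, so many of these need not differ. Among changed genes of at least median level whose symbol is not a clone identifier, the largest rises belonged to SPINK1, a serine peptidase inhibitor gene, with a log2 fold of 6.17, and to rpe65a, a retinoid isomerase gene of the retinal pigment epithelium, with 5.80, in the authors' deposited table. They were followed there by pfkpa (5.36), slc15a4 (5.31), atraid (5.16), ndnf (4.94), hk2 (4.83), cdc42ep3 (4.81), ablim3 (4.73) and itga6b (4.47). slc15a4 encodes a peptide and histidine transporter of endolysosomes. The largest falls among the same kind of genes in the authors' deposited table were those of col10a1a, a type X collagen gene, at -9.75, the glycogen phosphorylase gene pygma at -8.32 and the ghrelin gene ghrl at -7.24. Next came plcl1 (-7.18), gngt1 (-5.38), the neuropeptide gene npb (-5.33), gnat1 (-4.64), elovl4b (-4.60), syngr3b (-4.22) and the glucokinase gene gck (-4.18), again from the authors' deposited table. The levels of col10a1a, pygma and plcl1 were only 11.4, 4.08 and 3.40. Their implied standard errors were 1.61, 2.11 and 1.66 on the log2 scale, so the size of these falls is uncertain. SPINK1 lies 1.53 Mb from rraga on chromosome 14.

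**Figure D1:**
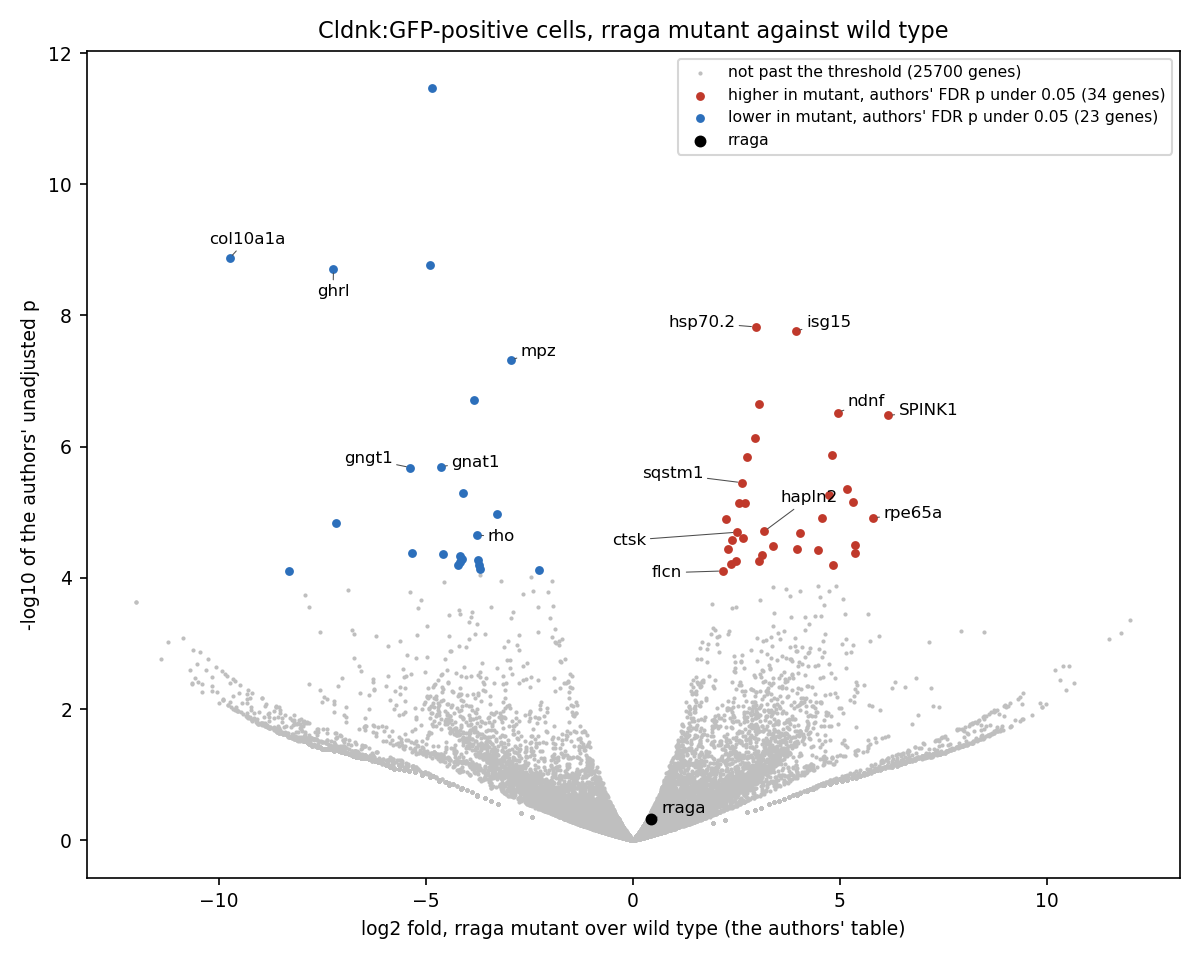
Log2 fold of rraga mutant over wild type (x axis) against -log10 of the unadjusted p (y axis) for 25757 genes of the authors' deposited table. Red and blue points are the 34 genes higher and the 23 lower in the mutant with an FDR adjusted p under 0.05, grey points are the others, and the black point is rraga at a log2 fold of 0.44.

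In the lysosomal list, 2 of the 79 members rose by the authors' adjustment and 77 did not pass it. These were the cathepsin genes ctsk (chromosome 16, 29558314 to 29567926; log2 fold 2.51, adjusted p = 0.0227) and ctsa (chromosome 6, 55386994 to 55411507; log2 fold 2.29, adjusted p = 0.0331) in the authors' deposited table. Adjusted over the list alone, 11 rose and 1 fell, the latter being naglu at a level of 1.41. The list's median of 0.87 stood at percentile 100 among 10000 random lists matched on level, whose central 95% ran from -0.03 to 0.30. The v-ATPase list also stood at percentile 100, against a central range of -0.08 to 0.40. None of its 25 subunits passed the authors' threshold, 12 were higher at an unadjusted p under 0.05, and 1, atp6v0e1, rose when adjusted over the list alone. Its members of highest level, atp6v1g1 and atp6v1e1b, had log2 folds of 0.85 (p = 0.133) and 1.17 (p = 0.0371) in the authors' deposited table. Markers of microglia and macrophages, which are rich in lysosomes, had a median of 0.16 over 39 genes, at percentile 69.8. The 10 macrophage markers of level 10 or more had a median of 0.55 at percentile 97.3, just inside the central 95%, and no marker of the list passed the authors' threshold, while 2 rose when adjusted over the list alone. The most abundant of them, apoc1 and apoeb, had log2 folds of -0.26 and -0.15 in the authors' deposited table.

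sqstm1 (chromosome 14, 16460339 to 16465752) rose with a log2 fold of 2.63 at a level of 532 and an adjusted p of 0.00714 in the authors' deposited table. It lies 2.67 Mb from rraga. It was the 1 gene of 56 on the autophagy and MiT-TFE list that changed, by the authors' adjustment and adjusted over the list alone. That list had a median of 0.09 and a mean of -0.07, and its percentile was 47.4. flcn (chromosome 16, 13928377 to 13955930) rose with a log2 fold of 2.17 and an adjusted p of 0.0477 in the authors' deposited table. It was likewise the 1 gene of 44 on the Rag-Ragulator, FLCN and mTORC1 list that changed under either adjustment. The median of this list was 0.17, at percentile 69.1.

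On the myelin list of 38 genes, 16 were higher and 22 lower, with a median of -0.23 at percentile 0.02, or 11.3 with random lists not matched on level. mpz, which encodes myelin protein zero (chromosome 2, 44406484 to 44429948), fell with a log2 fold of -2.96 at a level of 1110 and an adjusted p of 2.34e-04 in the authors' deposited table. hapln2, a link protein gene of the matrix at nodes of Ranvier (chromosome 16, 29369348 to 29374324), rose with 3.17 and an adjusted p of 0.0227 in the authors' deposited table. Adjusted over the list alone, 2 rose (hapln2 and gpr37b) and 3 fell (mpz, plp1b and cd59). Chosen after their values were seen, plp1b had a log2 fold of -1.89, cd59 -1.57, gpr37b 3.80, cldnk -0.82 and mbpa 0.23 in the authors' deposited table. mbpa was the most abundant gene of the list, at a level of 5321. Genes of the oligodendrocyte lineage and its precursors had a median of 0.25 over 32 genes (percentile 82.7), and none changed under either adjustment. Their most abundant members, olig2 and id2a, had log2 folds of -0.69 (p = 0.267) and 1.3 (p = 0.0132) in the authors' deposited table. Cholesterol and fatty acid synthesis genes had a median of -0.15 over 37 genes (percentile 6.7), with none changed, and elovl1b and elovl6 had -0.21 and -1.28 in the authors' deposited table. mpz is also on the list of Schwann cell and neural crest markers, in which it was the 1 gene of 20 past the authors' threshold, and adjusted over that list alone 2 fell. That list, of which 4 genes are on another list too, had a median of 0.66 (percentile 99.3) and a mean of -0.02.

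**Figure D2:**
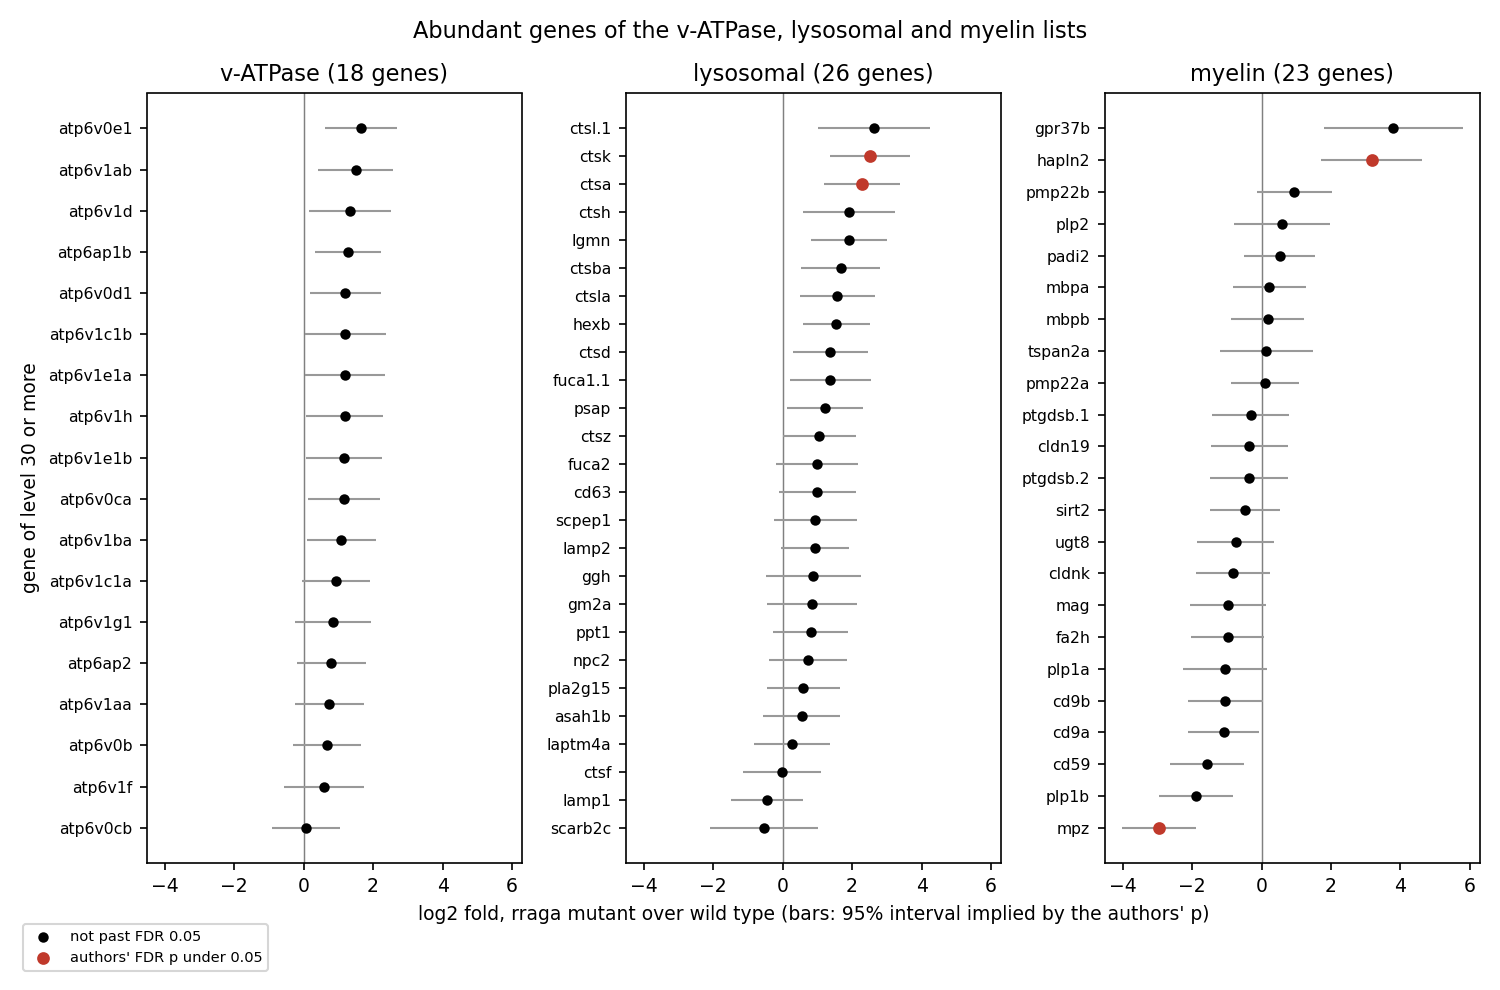
Log2 folds of rraga mutant over wild type (x axis) for the 18 v-ATPase, 26 lysosomal and 23 myelin genes of level 30 or more, 1 gene per line. Points are the values of the authors' deposited table, red where the FDR adjusted p is under 0.05, and bars are the 95% intervals that the p implies under a normal test. The bar lies above 0 for 11 v-ATPase and 12 lysosomal genes, and the myelin genes spread from mpz at -2.96 to gpr37b at 3.80.

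Of 32 glycolysis genes, 22 were higher, with a median of 0.51 at percentile 99.8, and 29 did not pass the authors' threshold. pfkpa, eno1b and hk2, which encode phosphofructokinase, enolase and hexokinase, rose under both adjustments, with log2 folds of 5.36, 3.96 and 4.83 and levels of 6.65, 36.5 and 3.77 in the authors' deposited table. Of the 38 dissociation and stress response genes, 32 were higher, with a median of 0.44 at percentile 99.7. The inducible chaperone genes hsp70.1, hsp70.2, hsp70.3 and hsp70l rose with log2 folds of 3.06, 2.96, 3.05 and 2.36 in the authors' deposited table, and 6 genes rose when adjusted over the list alone. hsp70.1, hsp70.2 and hsp70.3 are close copies next to each other on chromosome 3, so how reads were divided among them is uncertain. The immediate early genes junbb and fosab, chosen after their values were seen, had 0.45 and 0.42 in the authors' deposited table.

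None of the genes on the following 6 lists changed under either adjustment. The 13 mitochondrially encoded genes were all higher, with a median of 0.47 at percentile 98.2 (88.2 against unmatched lists), and mt-co2 and mt-atp6 had 0.35 and 0.47 in the authors' deposited table. The 85 nuclear oxidative phosphorylation genes had a median of 0.07 (percentile 9.7) and a mean of -0.06, and atp5g1 and atp5l had -0.09 and 0.08 in the authors' deposited table. Of 78 cytosolic ribosomal protein genes, 71 were lower, with a median of -0.14 at percentile 0 (11.9 against unmatched lists), and rpl32 and rplp0 had -0.10 and -0.27 in the authors' deposited table. The SD of the log2 fold across the 76 ribosomal protein genes of level 30 or more was 0.13, against a median implied standard error of 0.57. The implied errors thus did not match the scatter of these genes. Endoplasmic reticulum chaperone and unfolded protein response genes had a median of -0.19 over 29 genes (percentile 0.19, or 18.6 against unmatched lists), with xbp1 at -0.09 and hspa5 at -0.15 in the authors' deposited table. DNA replication and mitosis genes had a median of -0.30 over 37 genes (percentile 0.225, or 7.0 against unmatched lists), with hmgb2a at 0.10 and pcna at 0.13 in the authors' deposited table. ATF4 and amino acid response genes had a median of 0.28 over 36 genes (percentile 89.1), with atf4b at 0.55 and cebpb at -0.08 in the authors' deposited table.

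Markers of other tissues were abundant in the sorted cells. The 36 genes of exocrine pancreas, liver and gut held 17.4% of the summed level and 10 of the 20 places of highest level, against 2.81% for the myelin list. They were lower in the mutant in 27 of 36 cases, with a median of -0.55 at percentile 0, and 1 fell when adjusted over the list alone. apoa2 and apoa1b had the highest levels of all genes, 23442 and 22959, with log2 folds of -0.57 and -0.57 in the authors' deposited table. Erythrocyte genes went the other way, with 14 of 18 higher and a median of 1.51 at percentile 100. The globin gene hbae1.3 rose with 2.65 in the authors' deposited table, and 7 genes rose when adjusted over the list alone, although globin genes are similar copies among which reads can be divided. In the photoreceptor and lens list of 43 genes, gnat1, gngt1, rho and sagb of rods fell with log2 folds of -4.64, -5.38, -3.76 and -4.18, and the ultraviolet opsin gene opn1sw1 of cones rose with 4.04, in the authors' deposited table. Adjusted over that list alone, 4 rose and 6 fell, and its median was 0.18 (percentile 71.6).

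hepacama, which encodes a glial adhesion protein, fell with -2.28 and an adjusted p of 0.0470 in the authors' deposited table. It was the 1 gene past either adjustment among 26 radial glia and astrocyte markers, whose median was -0.38 (percentile 0.01, or 7.03 against unmatched lists). Neuronal markers had a median of -0.27 over 40 genes (percentile 1.57, or 8.27 against unmatched lists), with elavl3 at -0.83 and snap25b at 0.68 in the authors' deposited table. Epidermal markers had a median of 0.44 over 26 genes (percentile 98.2, or 94.5 against unmatched lists), with icn at 1.3 and krt18 at -0.09 in the authors' deposited table. Skeletal muscle markers had a median of -0.01 and a mean of 0.11 over 34 genes (percentile 17.0), with actc1b at 0.32 and pvalb2 at -0.86 in the authors' deposited table. Pigment cell markers had a median of -0.10 and a mean of 0.04 over 19 genes (percentile 22.8), with gch2 at 0.43 and tyrp1b at 1.28 in the authors' deposited table. Endothelial markers had a median of -0.04 over 24 genes (percentile 56.3), with cldn5b at -2.93 and fli1a at 0.37 in the authors' deposited table. No member of these last 5 lists passed the authors' threshold, and adjusted over the list alone 1 muscle and 1 pigment gene fell and no other changed.

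**Figure D3:**
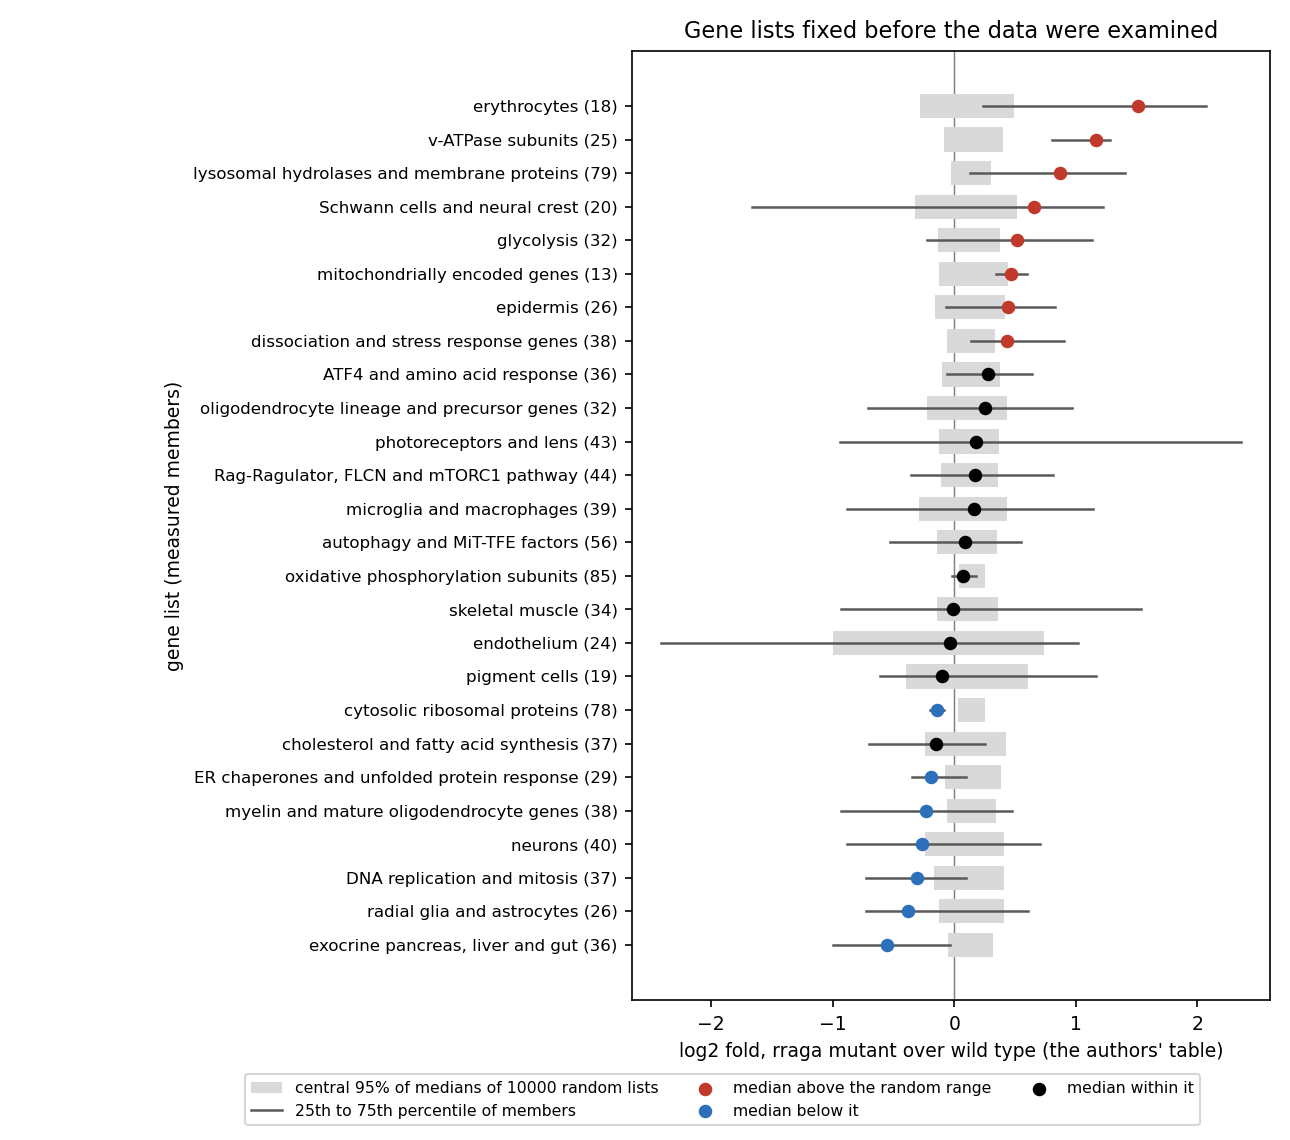
Median log2 fold of rraga mutant over wild type (x axis) for the 26 gene lists, with the number of measured members in parentheses. Dark lines span the 25th to 75th percentile of the members, and grey boxes the central 95% of medians of 10000 random lists matched on level. Red medians (8 lists) lie above that range, from stress response genes at 0.44 to erythrocytes at 1.51, and blue medians (7 lists) lie below it.

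For some lists the median differed by over 1.5 times or in sign without the weakly expressed members. Among members of level 10 or more, a setting chosen after the data were seen, the median was -0.74 for neurons (percentile 0), -0.60 for radial glia (percentile 0), 0.40 for the Rag-Ragulator, FLCN and mTORC1 list (percentile 96.2), 0.25 for the autophagy list (percentile 79.0), 0.48 for the oligodendrocyte lineage (percentile 94.1) and -0.19 for DNA replication and mitosis (percentile 1.4). It had the other sign for photoreceptors and lens (-0.03, percentile 5.77), cholesterol and fatty acid synthesis (0.04, percentile 27.4), pigment cells (0.17, percentile 53.4) and skeletal muscle (0.04, percentile 16.7). The myelin median was -0.35 (percentile 0), and the endothelial list had only 1 such member.

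The medians of 15 of the 26 lists lay outside the central range, 8 above and 7 below, where 1.3 would by chance, but genes of a list vary together, so the percentiles describe these values and are no test, and 7 lay outside against unmatched lists. The number of changed genes depended on the adjustment, with 113 in place of 57 when the authors' deposited p was adjusted over genes of level 10 or more. Of these 113, 51 were among the 57 and 62 were not. The 6 changed genes under level 10, pfkpa and hk2 among them, were left out by that setting.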

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

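The direction of every named gene is the authors' and was the same under each alternative, since these change only the adjustment. Their calls were less stable. At the authors' FDR p under 0.01, 22 of the genes named by the rule were no longer called, among them ctsk, ctsa, flcn, hapln2 and hepacama. Requiring an absolute log2 fold of at least 1 could remove none of the 57 changed genes, because their smallest was 2.17. The count was 20 at the authors' FDR p under 0.01 and, with fewer genes tested, 90 when adjusted over genes of level 1 or more and 113 over genes of level 10 or more; this level is the higher genotype mean, so such a filter is not independent of the fold. Chosen after the data were seen, adjustment over genes with a p only gave 62 and the authors' Bonferroni p gave 14. The share of higher genes lay between 53.3% and 59.6%, and rraga was not past the threshold under any adjustment tried. With random lists not matched on level, 7 lists in place of 15 lay outside the central range, because the random medians were then drawn from genes of all levels. The lists now inside it were myelin (percentile 11.3), endoplasmic reticulum chaperones (18.6), ribosomal proteins (11.9), mitochondrially encoded genes (88.2), DNA replication and mitosis (7.0), neurons (8.27), radial glia (7.03) and epidermis (94.5). With members of level 10 or more, a setting added after the data were seen, epidermis was inside the range as well (96.6); the cause was not tested. No paired analysis was possible because the table holds no values per replicate. For the same reason the planned refits with other tools, size factors, filters, pseudocounts or variance models, the replicate left out in turn, and list tests with an estimated correlation were not run. No gene under level 3 was called. The median implied standard error was 1.57 at levels of 1 to 3 and 2.02 under 1.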

Other observations

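The tests on macrophage, oxidative phosphorylation, myelin, Schwann cell, rod and cone genes and on genes near rraga were chosen after the results they bear on, or part of their values, had been seen. The tests of interferon and pigment epithelium genes were set before those values were examined, on lists added after the first results. Several genes on no fixed list also changed, and they are named here because of their values. The ubiquitin-like interferon-response gene isg15 rose with a log2 fold of 3.93 and an adjusted p of 9.89e-05 in the authors' deposited table, and slc16a1a, a monocarboxylate transporter gene, rose with 2.94. The neighbouring genes zgc:198419 and zgc:109934 on chromosome 3 rose with 2.4 and 2.76 at levels of 1548 and 1002 in the authors' deposited table. The aquaporin gene aqp12 fell with -3.76 there, and the unnamed gene BX000438.1, with the smallest p of all (3.45e-12), fell with -4.85.

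A wider rise of interferon-stimulated genes may lie behind isg15, but the median of 28 other such genes was 0.38, at percentile 89.7 of matched random lists, which neither shows nor excludes it, and 1 of them fell when adjusted over the list alone. More RNA of the retinal pigment epithelium, which the sort for Cldnk:GFP should remove, is likewise a possible explanation for rpe65a, and the other 16 genes of that list had a median of 0.63 at percentile 96.8, just inside the central 95% (with rpe65a, 17 genes, 0.76 and 98.6). Linked alleles around the mutated locus may also account for sqstm1 and SPINK1; without these genes, 3 of 75 genes of level 1 or more within 5 Mb of rraga (4.0%), of which si:ch211-125c23.3 and cx31.7 overlap each other, had a p under 0.01 in the authors' deposited table against 3.67% elsewhere (one-sided Fisher's exact p = 0.523), which leaves this open.

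The higher v-ATPase and lysosomal values could come from scaling, or from more macrophage RNA in the mutant cells although the sort for Cldnk:GFP should remove macrophages. Oxidative phosphorylation genes, which are also abundant, had a lower median than the v-ATPase genes (difference -1.09, 95% bootstrap interval over genes -1.16 to -0.77) and than the lysosomal genes (difference -0.80, -0.96 to -0.62), which argues against a shift of all abundant genes in this comparison. Bootstrap intervals here and below resample genes, which vary together, and carry no spread between replicates. They describe these values only. The 24 non-lysosomal macrophage markers of level 1 or more differed from the v-ATPase genes by -0.82 (-1.44 to -0.24), on the side against macrophage RNA as the whole source of the v-ATPase values. With only the 8 markers of level 10 or more the interval was -1.39 to 0.59, so the question is not settled. Against the lysosomal list the difference was -0.53 (-1.18 to 0.04), so for those genes a macrophage share stays open. A response of the oligodendrocytes to the loss of rraga stays a hypothesis beside it, not separable here from a change in cell makeup because the sorted cells were measured as a whole.

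Fewer myelinating cells among the sorted mutant cells could lower mpz, plp1b and cd59. Such a loss would lower the myelin genes alike only if their RNA came from those cells alone, which was not tested. All 31 myelin genes of level 10 or more, with mpz, plp1b and cd59 included, had a weighted mean log2 fold of -0.40 (95% interval -0.81 to 0.01). The interval that the authors' p implies for mpz ended at -1.90. mpz was picked because it passed the threshold, which by itself places its interval well below 0. The comparison therefore cannot decide whether such a loss is the whole source of the fall of mpz. A smaller loss, and its share in plp1b and cd59, which did not pass the authors' threshold and whose intervals ended at -0.81 and -0.51, stay open: the mean was -0.29 (-0.67 to 0.09) over the 30 genes without mpz, and -0.30 (-0.57 to -0.02), on the side of a smaller loss, over 26 without mpz, plp1b, cd59, hapln2 and gpr37b, a set picked by its values. mpz is also a Schwann cell gene, and fewer Schwann cells among the sorted mutant cells is another candidate explanation. Whether Schwann cells carry Cldnk:GFP, and so pass the sort, was not tested here. The 13 Schwann cell and neural crest markers of level 1 or more that are on no oligodendrocyte list had a median of 0.70. Its 95% bootstrap interval of -1.60 to 0.99 does not decide the question. The genotype itself stays an open explanation of the myelin differences.

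The 5 rod genes seen first (rho, gnat1, gngt1, saga and sagb) had a median of -4.18 and the 5 cone genes seen first (opn1sw1, opn1sw2, pde6c, gngt2a and gnat2) one of 2.67, values of genes picked for this contrast. Less retinal RNA of every kind would lower cone genes about as much as rods, but 7 other cone genes of level 10 or more ran from -1.03 (pde6h) to 1.68 (opn1lw2) in the authors' deposited table, with a median of 0.56 (95% bootstrap interval -0.38 to 1.19), while the implied intervals of the 4 changed rod genes all ended at or below -2.02. These 4 rod genes were picked because they passed the threshold, which by itself places their intervals well below 0. The comparison therefore covers those 4 genes only and cannot decide whether such a loss is the whole source of the rod values. Whether rods and cones moved in opposite directions as classes stays open: all 11 further rod genes were lower, while of the 21 further cone genes 11 were higher and 10 lower, and the medians differed by 1.45 (95% bootstrap interval 0.40 to 2.73), but neither the rod median of -0.95 (percentile 3.56) nor the cone median of 0.50 (percentile 94.7, mean -0.17) left the central 95%, and at median levels of 1.45 and 2.59 errors are wide. The sort for Cldnk:GFP should remove photoreceptors, and rho still had a level of 1128 in the authors' deposited table.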
